A study of Mus musculus with 10 samples.

How the data were processed

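Messenger RNA of single testes from 10 male mice of the inbred strain C57BL/6N was measured on 1-colour Agilent mouse gene expression arrays, 1 array per animal. Per the labels, the RNA was taken with either of 2 column kits of different size and was labelled with the dye Cy3 by a low-input amplification kit. Which kit served which testis, the RNA integrity of each sample and the litters were not given in the sources used here. Litter mates may therefore stand within a group, and the p-values treat the 10 animals as independent.

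Each array's file held spot intensity values that the authors deposited as scanner output of Agilent Feature Extraction 12.0.3.1, per the submitters' processing notes. Per the file headers, the processed intensity was background-subtracted and detrended within an array and was not normalised between arrays. Raw spot and local background intensity values and the flags for background, saturation and outlier spots came from the same deposited files. The headers named mm9 as the build behind the probe annotation.

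The authors also deposited a table of their own comparison. It held scaled intensity values, log2 ratios, p-values and q-values for 2266 probes, and each array's scaled intensity was its processed intensity times 1 constant. The p-values of the authors' deposited table equalled those of an equal-variance comparison of linear intensities, with a largest difference of 2.8e-09. How its q-values were made was not given in the sources used here. A further 10 columns of per-sample values in the table were not used here. The log2 ratio in the authors' deposited table was formed with R replicate 1 on its control side and C replicate 5 on its test side, against the deposited group labels. Groups were taken from the labels throughout, and the table's grouping was run as an alternative.

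Spots of the same probe were averaged after control spots and outlier spots were left out. The log2 of the processed intensity minus the array's 75th percentile was the unit of all values and is called the log2 signal. Probes well above background on at least 5 of the 10 arrays were tested, which left 33851 of 56605 probes, and 2 more were dropped for a missing value. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) with Benjamini-Hochberg adjustment, and a call is an adjusted p under 0.05. The study's criterion adds a fold above 1.5 or under 0.66. No pairing of the animals was given by the labels, and no paired test was run.

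Probes were named through their accession in a gene table of the assembly GRCm38 where it held the accession, which was so for 33767 probes, and 234 kept or updated the deposited symbol. In all, 34001 probes took 23550 symbols, and the chromosome of a gene is that of the same table. A gene stood for its brightest tested probe, which gave 16835 genes. Of 2160 called genes with another tested probe, 68.7% had every other probe of the same sign, and 236 had another probe called the opposite way.

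The test, the filter, 33 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 10 genes with the largest fold in each direction among those past the study's criterion, up to 4 members of smallest p of each list described, and 29 testis genes whatever their values, of which some are not reported here. Genes named outside this rule are said to be so. Lists were tested with limma's camera at a correlation of 0.01, beside an estimated correlation, limma's fry and an exact 2-sided permutation test of each array's list mean, whose smallest possible p is 0.00794. A list's members were counted over all genes tested and again adjusted over the list alone. Insl3 was not analysed here, because no probe took that name.

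Where a gene was not well above background on any array of a group, only a lower bound of its fold is given. The bound sets the brighter group's mean against the mean, per array, of the higher of the dim probe's own signal and the lowest signal among probes well above background. Members of multigene families may share signal across copies, and their values are uncertain for that reason. The number of arrays limits the precision.

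The procedure was tested on simulated data of 33851 probes and 5 arrays per group, with 200 changed probes. It recovered 72.0% of probes changed 2-fold and 96.0% of those changed 4-fold, and it called 12 of 33651 unchanged probes. A simulated change of 1 on the log2 scale was fitted as 0.98 on average, and 0 lists were called where none had been changed. The simulated noise was independent between probes, while the estimated correlation was 0.62 within the Sertoli list and 0.80 within the ribosomal list. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes.

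Alternatives covered normexp background correction, quantile normalisation, scaling to each array's median, the authors' scaling factors, no filter or a stricter filter, a trended and robust variance, array weights, the slide as a block, the mean of a gene's probes and leaving out each array. The mean spot intensity was not used here, and the median spot intensity took its place in the normexp correction. The table's grouping, the 2 arrays it places otherwise and each slide alone were added after the data had been seen, as were the comparison of chromosomes and that of probe classes. The group labels and the slide were not fully crossed, since 4 R and 2 C arrays shared slide 1, and 1 R and 3 C arrays shared slide 2. Each slide was scanned in its own scan. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.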

Results

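The data cover testes of male mice at 6 weeks of age, when spermatogenesis has reached the last stages. The 5 R animals were sons of dams that received 50% of the control intake from 6.5 days after mating, and they were raised by unrelated control dams. The 5 C animals were sons of freely fed dams and stayed with their own mothers, so that fostering differed between the groups along with the prenatal diet. The series concerns maternal undernutrition, fetal testosterone and later sperm number, and the arrays ask which testis transcripts differ at this age. Between 56.6% and 67.4% of the probes of an array were well above background, and no spot was saturated. The 75th percentile of the processed signal lay between 804 and 1019, with means of 918 in C and 931 in R. The lowest exact permutation p over 6 quality measures was 0.0873 (adjusted p = 0.524). It was that of the median signal, at 83.6 ± 13.2 in C and 97.1 ± 8.37 in R (SD). Scaling to the 75th percentile leaves the array medians unequal, so that shifts of dim and of bright genes depend on the reference.

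In the R testes, limma's camera called lower the gene lists of Sertoli cells, which nurse the germ cells, and of steroid-producing Leydig cells. It also called lower the list of macrophages and other leukocytes. In these lists 18 of 27, 10 of 23 and 9 of 21 members were lower, with medians of −0.51, −0.28 and −0.53 on the log2 scale. The list of the sperm flagellum and its dynein motors and that of endothelial cells were called higher, with 10 of 28 and 4 of 13 members higher and medians of 0.25 and 0.35 (0.04 and 0.14 with each array's median as reference). None of these list calls held with an estimated correlation (adjusted p = 0.78), nor did those of the oxidative stress defence, the cell cycle, ribosomes and oxidative phosphorylation, which were called lower. Markers of late spermatocytes, round spermatids and elongating spermatids had medians between −0.01 and 0.01. These values are relative to the bulk of the array, since the median over all genes was −0.03 with the 75th percentile as reference and −0.23 with each array's median as reference.

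Of 16835 genes, 5793 (34.4%) were called by limma, 2426 higher and 3367 lower in R, and 716 and 950 of them passed the study's criterion of fold and adjusted p. The groups did not overlap at 4905 genes (29.1%, against 0.794% by chance). Of 33851 probes, 13059 were called, 7261 higher and 5798 lower, and 5309 met the study's criterion. With each array's median as reference 4029 of 14597 called probes (27.6%) were higher, against 55.6% in the main scaling, so that the balance of directions depends on the reference. With the slide as a block 17853 probes were called. Among the arrays of slide 1 alone 13193 were called, and among those of slide 2 (3 C and 1 R) limma called 0, with 8750 at an unadjusted p under 0.05.

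The direction of every comparison rests on the deposited group labels, and the authors' deposited table groups 2 arrays otherwise. With the table's grouping limma called 0 probes (2567 at an unadjusted p under 0.05, lowest adjusted p = 0.461), and the table's own test called 0 (2195 at p under 0.05). That table itself lists 2266 probes, all with a q of 0.515. Without these 2 arrays 6116 probes and 2291 genes were called. On principal component 1, which carried 60.4% of the variance, R replicate 1 scored 49.2 beside 33.6 to 44.1 for the other R arrays, and C replicate 5 scored −29.5 beside −13.9 to −28.8 for 3 of the other C arrays. C replicate 2 stood apart at −123, and without it 12833 probes and 5511 genes were called.

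**Figure D1:**
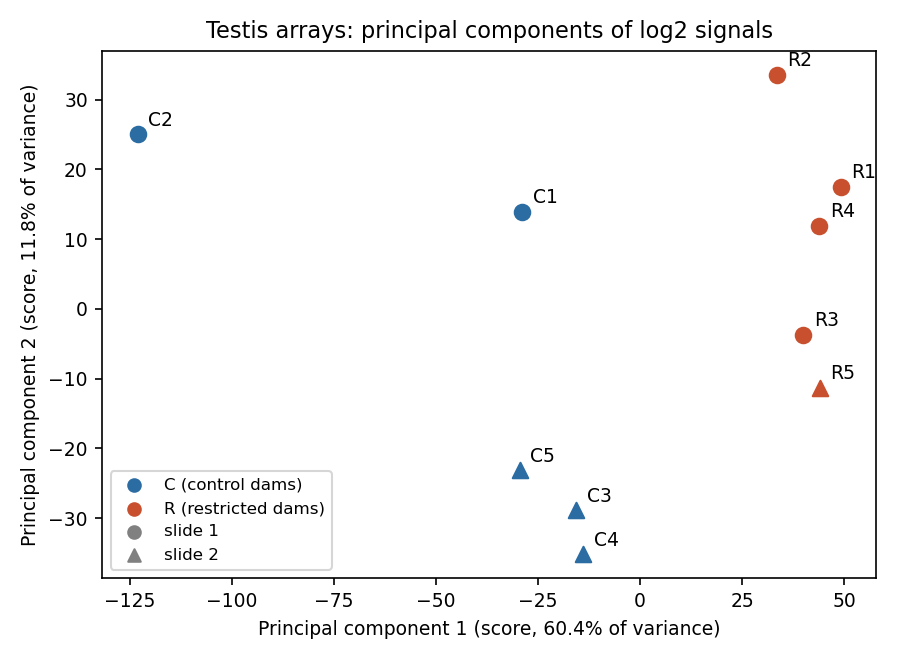
Scores of the 10 arrays on principal components 1 (60.4% of variance) and 2 (11.8%) of the log2 signals, coloured by labelled group and shaped by slide. The R arrays lie between 33.6 and 49.2 on component 1, and the C arrays lie below 0 with C replicate 2 at −123.

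The genes with the largest rise included receptor genes and 1 transcription factor gene. Trpm1, a cation channel of retinal bipolar cells, rose 3.73-fold (95% interval 2.24 to 6.24, n = 5 per group, adjusted p = 0.00385). Pou4f1, a transcription factor of sensory neurons, rose 3.05-fold from a log2 signal of 1.16 ± 0.30 to 2.77 ± 0.67 (SD), and Tdgf1, a co-receptor of Nodal signalling, rose 3.19-fold. Il22ra1, a subunit of the interleukin-22 receptor, Mrgprg, an orphan receptor, and Lypd6b rose 3.49-fold, 3.38-fold and 3.29-fold. Angptl7, an angiopoietin-like secreted protein, had the highest estimate at 7.81-fold, with an interval of 1.95 to 31.3. Gabra2, a subunit of the GABA receptor, rose 4.52-fold, and both it and Angptl7 were above background on 2 of 5 C arrays. Vmn1r31, of the vomeronasal receptor family, rose 3.61-fold but was above background on 1 C array and 4 R arrays, and Apol10a rose 3.21-fold from 4 C arrays. Over the mean of all their probes the log2 changes of Trpm1 and Lypd6b were 0.99 and 0.99, against 1.90 and 1.72. R replicate 5, the only R array of slide 2, lay within the range of the C arrays for Il22ra1 (−2.98), Mrgprg (−2.12), Tdgf1 (0.77) and Gabra2 (−4.74), while the 4 R arrays of slide 1 lay above it. Trpm1 (0.20), Pou4f1 (1.68) and Lypd6b (−2.06) in the same array were closer to the C arrays than to the other R arrays. Copies of both families, Vmn1r and Apol10, may share signal. Angptl7 (adjusted p up to 0.0670) and Apol10a (up to 0.0727) lost their calls when any 1 of 7 arrays was left out. The log2 change of Angptl7 was 2.97, and 3.83 without C replicate 4, and that of Apol10a was 1.68, and 1.12 without C replicate 2.

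The genes with the largest fall included, by probe annotation, the beta-globins Hbb-b1 and Hbb-b2, a macrophage lysozyme and 5 genes on chromosome X. Sft2d1, a Golgi transport protein, fell from −0.68 ± 0.29 to −2.43 ± 0.20 (SD, n = 5), which is 3.38-fold (95% interval 2.68 to 4.25, adjusted p = 8.5e-04). Tbx22, a T-box transcription factor on chromosome X, was 2.73-fold lower with an adjusted p of 1.7e-04. The other probe of Tbx22 had the opposite sign, and the call was lost over the mean of both (adjusted p = 0.244). Mageb4, a cancer-testis antigen gene, was 2.78-fold lower, and Fthl17f, a ferritin-like gene, was 2.75-fold lower with 4 C arrays and 1 R array above background. Prrg1 and Enox2, also on X, were 3.31-fold and 3.01-fold lower, with 2 and 3 R arrays above background. Cth, the cystathionine lyase that makes cysteine, was not well above background on any R array and was at least 1.45-fold lower (adjusted p = 0.00245). Hbb-b1 was 4.81-fold lower, Hbb-b2 3.02-fold lower and Lyz2 3.96-fold lower, and Hbb-b1 and Lyz2 were above background on 2 of 5 R arrays. Hbb-b1 lost its call without C replicate 5 or without R replicate 3 (adjusted p up to 0.0589), and its log2 change ranged from −2.68 to −1.68 as each array was left out. Sequence shared within the globin, Mageb and Fthl17 families makes these values uncertain. The probes named Hbb-b1 and Hbb-b2 may report another beta-globin copy, so their folds need not be those of these genes.

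**Figure D2:**
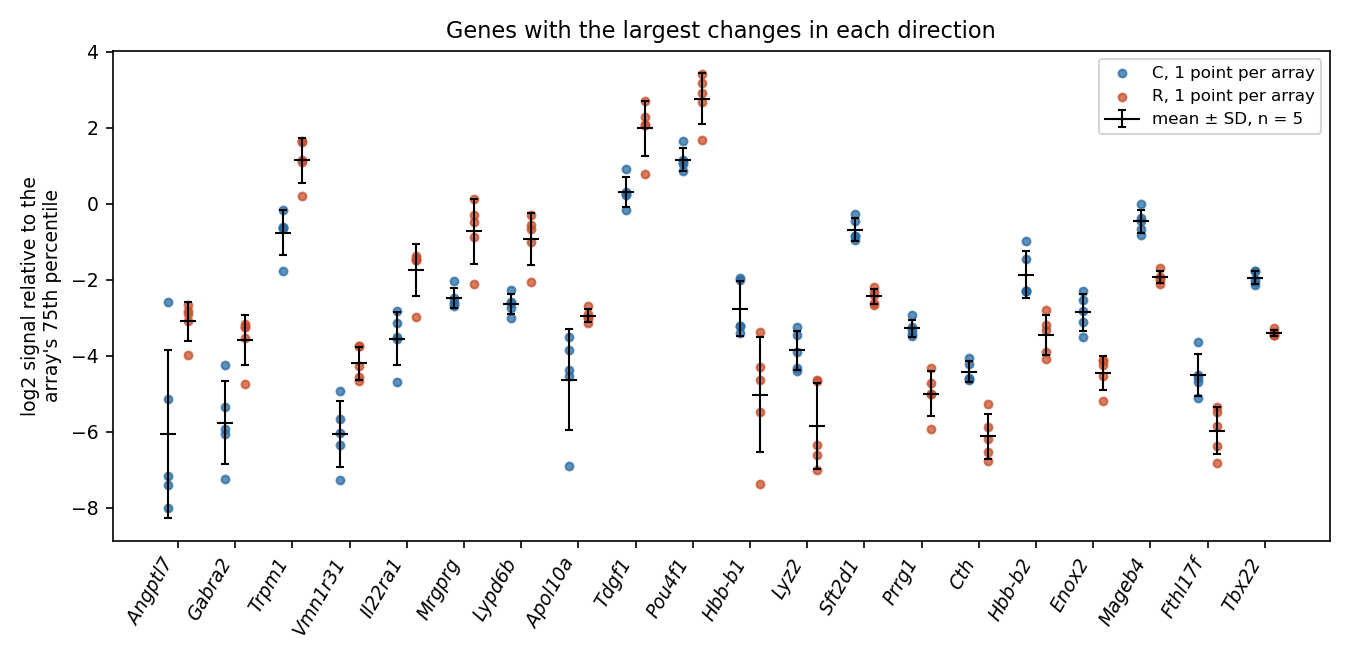
Log2 signal relative to the array's 75th percentile for the 10 genes with the largest rise and the 10 with the largest fall, with 1 point per array and the mean ± SD of 5 arrays per group. The R arrays of Sft2d1 average −2.43 and its C arrays −0.68, while Angptl7 spreads widely in C (SD 2.22).

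The Sertoli cell list had the lowest camera p of the somatic cell lists. Of 27 tested members 18 fell and 1 rose (21 lower and 1 higher when adjusted over the list alone), with a median of −0.51. The list was lower by camera (adjusted p = 2.6e-04, and adjusted p = 0.78 with an estimated correlation). Ctsl, a lysosomal protease, fell 2.03-fold, Kitl, the ligand of the germ cell receptor Kit, 1.96-fold, Cst9 1.79-fold and the tight junction gene Tjp1 1.35-fold, though neither of the other 2 probes of Kitl had its sign and the call was lost over their mean (adjusted p = 0.29). Fshr, the receptor of follicle-stimulating hormone, was 1.58-fold lower (adjusted p = 0.0378, up to 0.0859 when any 1 of 6 arrays was left out), and Inhbb, an inhibin subunit, was 1.40-fold lower (0.0214, up to 0.0515 without R replicate 3 or 4). Sox9 did not pass, at a log2 change of −0.06 ± 0.22 (SE). The member that rose was Rhox8, a homeobox gene of Sertoli cells that responds to androgen, at 1.88-fold. The list's median was −0.67 with the slide as a block, −0.80 within slide 1 and −0.30 within slide 2.

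Part of the Leydig cell and steroid pathway list was lower. Of 23 tested members 10 fell and 0 rose (10 and 0 when adjusted over the list alone), with a median of −0.28. Camera gave an adjusted p of 0.0114 (adjusted p = 0.78 with an estimated correlation, 0.0719 with each array's median as reference, 0.0785 with array weights). Hsd3b1, which turns pregnenolone into progesterone, fell 1.70-fold, the mitochondrial protein Tspo 1.70-fold, the imprinted gene Dlk1 2.08-fold and the steroid reductase gene Akr1c14, above background on 3 C and 2 R arrays, 1.68-fold. Cyp17a1, which leads to androgens, was 1.58-fold lower (95% interval 1.16 to 2.15, adjusted p = 0.0313), and Hsd17b3, which makes testosterone, was 1.48-fold lower (1.11 to 1.97, 0.0399). Both calls were lost when any 1 of 4 and of 8 arrays was left out, at adjusted p up to 0.0745 and 0.0905. Star, the carrier of cholesterol into mitochondria, did not pass (1.21-fold lower, 0.716 to 2.03), nor did Cyp11a1 (1.18-fold, adjusted p = 0.0726), Hsd3b6 or the luteinising hormone receptor Lhcgr, above background on 2 R arrays (0.513 and 0.408). Cyp11a1 was called lower with the slide as a block (adjusted p = 0.0104), with the array median as reference (0.0216) and without C replicate 5 (0.0456). Hsd17b3 was not called with array weights (0.0895). The list's median was −0.43 with the slide as a block, −0.59 within slide 1 and −0.29 within slide 2. Of 17 genes that respond to androgen in the testis 9 fell and 1 rose (13 and 1 when adjusted over the list alone), with a median of −0.45 and a camera adjusted p of 0.00518 (adjusted p = 0.78 with an estimated correlation, 0.0719 with the array median as reference). Susd3 fell 1.70-fold and Serpina5 1.57-fold, while Rhox8, which stands in both this list and the Sertoli list, was the member that rose. Of genes named outside the rule, Rhox5 and Gata1 also stand in the Sertoli list (median −0.51) and Ptgds in the Leydig list. These lists are therefore not separate evidence. Corin fell 1.46-fold, but without R replicate 4 or 5 it did not pass (adjusted p up to 0.0538), and its log2 change was −0.55, and −0.30 over the mean of its probes. The androgen list's median was −0.60 with the slide as a block, −0.79 within slide 1 and −0.34 within slide 2. The 22 genes of cholesterol synthesis had 2 members higher and 2 lower (0 and 0 when adjusted over the list alone) and a camera adjusted p of 0.504.

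Other somatic cell lists were called in both directions. Of 21 macrophage and leukocyte genes 9 fell and 1 rose (10 and 1 when adjusted over the list alone), with a median of −0.53 and a camera adjusted p of 0.0245 (adjusted p = 0.78 with an estimated correlation, 0.115 with the array median as reference, 0.123 with array weights, 0.0830 over probes above background on all arrays, 0.0728 without C replicate 2). Mrc1, the mannose receptor, fell 1.89-fold and the complement gene C1qb 1.44-fold, while Itgam, an integrin of myeloid cells, rose 2.08-fold. The median was −0.57 with the slide as a block, −0.76 within slide 1 and −0.43 within slide 2. Of 13 endothelial genes 4 rose and 0 fell, with the same counts when adjusted over the list alone, and a median of 0.35 (0.14 with the array median as reference and 0.18 with quantile normalisation). The endothelial call had an adjusted p of 0.00718 (adjusted p = 0.78 with an estimated correlation, 0.0514 with quantile normalisation). Kdr and Flt1, receptors of vascular endothelial growth factor, rose 1.94-fold and 1.54-fold and Vwf 1.36-fold, and Eng rose 1.27-fold but lost its call when any 1 of 7 arrays was left out (adjusted p up to 0.0716) and with the array median (0.336) or quantile normalisation (0.265). The endothelial median was 0.36 with the slide as a block, 0.25 within slide 1 (adjusted p = 0.103) and 0.47 within slide 2. Of 6 blood genes 4 fell, with the same count when adjusted over the list alone, and a median of −0.92 (camera adjusted p = 0.0272, adjusted p = 0.78 with an estimated correlation). The blood call was lost without C replicate 2 (0.0582) and with the slide as a block (−0.88, adjusted p = 0.100), and its median was −1.29 within slide 1 and −0.21 within slide 2, which holds 1 R array. It was also lost with the array median as reference (0.110), quantile normalisation (0.0514), array weights (0.0785), no filter (0.0722) and the stricter filter (0.0600). Hbb-bt fell 2.21-fold and Alas2 1.52-fold, and each lost its call when any 1 of 3 arrays was left out (adjusted p up to 0.0593 and 0.0572). The probes named Hbb-b1, Hbb-b2 and Hbb-bt, all among the members that fell, may share signal from the same beta-globin transcripts. They need not be separate evidence.

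Adipocyte markers varied between arrays. No member of 11 passed, over all genes or when adjusted over the list alone, and the list's mean log2 signal was −2.07 ± 0.80 in C and −1.23 ± 0.51 in R (SD, n = 5, exact permutation p = 0.103). Cfd was at 1.91 in C replicate 2 and 2.86 in R replicate 2, against −6.77 to −2.06 in the other C arrays and −0.87 to 0.05 in the other R arrays, and its adjusted p was 0.112. Car3, Fabp4 and Plin4 had adjusted p of 0.0541, 0.125 and 0.104. Among the C arrays Cfd and Car3 were above background on 4 and Fabp4 on 3. Without C replicate 2 the list was called (adjusted p = 0.0370), as were Cfd (0.0141), Car3 (0.00387) and Fabp4 (0.00601), and with array weights Cfd, Car3, Fabp4 and Plin4 were called (0.00987, 0.00140, 0.00428 and 0.0269). Car3 also passed with a trended variance (0.0414), the authors' scaling factors (0.0470) and the mean of probes (0.0493). Smooth muscle and peritubular myoid genes (1 higher and 1 lower of 12, the same when adjusted over the list alone) had a camera adjusted p of 0.696, and epididymal genes (1 higher of 7, and 0 when adjusted over the list alone) one of 0.791.

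Within the germ line, the lower list medians lay at the early stages. Of 23 spermatogonial genes 8 fell and 3 rose, with the same counts when adjusted over the list alone, and the list did not pass (median −0.21, camera adjusted p = 0.121), though it was called with no filter (0.0234) and over the mean of probes (0.0354). Kit, the receptor of differentiating spermatogonia, fell 1.77-fold (95% interval 1.44 to 2.17, adjusted p = 0.00302), Stra8, a switch for meiosis, 1.72-fold, Rhox13 1.71-fold and Sohlh1 1.27-fold, while Zbtb16 did not pass (−0.21 ± 0.18, SE). Of 33 genes of meiotic synapsis and recombination 11 fell and 3 rose, again with the same counts when adjusted over the list alone, and the list missed the threshold (median −0.21, camera adjusted p = 0.0593). It was called with no filter (0.00448) and without C replicate 1 (0.0342), R replicate 3 (0.0384) or R replicate 4 (0.0444). Tex12, Hormad1 and Ythdc2 fell 2.19-fold, 1.96-fold and 1.95-fold and Sycp3 1.58-fold, while Sycp2, which also builds the synaptonemal complex, rose 1.46-fold. The log2 change of Hormad1 was −0.97, and −0.54 over the mean of its probes. The meiotic list's mean fell from 1.21 ± 0.08 to 0.98 ± 0.03 (SD, n = 5, exact permutation p = 0.00794, the smallest possible).

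The lists of late germ cells had medians close to 0. Of 24 late spermatocyte genes 1 rose and 1 fell (0 and 0 when adjusted over the list alone), with means of 4.03 ± 0.03 and 4.04 ± 0.03 (SD, n = 5). Pgk2 was 1.15-fold lower and Plk1 1.21-fold higher, and both lost their calls with the slide as a block (adjusted p = 0.0582 and 0.0573) and when any 1 of 7 arrays was left out (up to 0.0968 and 0.0910). With the array median as reference Plk1 was not called either (0.550), nor was Pgk2 with quantile normalisation (0.220) or the authors' scaling factors (0.125). Hspa2 differed by 0.02 ± 0.08 (SE). Of 31 round spermatid genes 2 rose and 3 fell (0 and 2 when adjusted over the list alone). Zpbp2 and Zpbp, of the acrosome, fell 1.25-fold and 1.34-fold, Actl7a rose 1.16-fold and Spata16 rose 1.15-fold, though the last changed sign with the array median as reference and Actl7a was not called there (adjusted p = 0.943) or with array weights (0.0591). Both lost their calls when any 1 of 7 (Actl7a, up to 0.0791) or 6 arrays (Spata16, up to 0.0741) was left out. Of 31 elongating spermatid genes 1 rose and 3 fell (0 and 1 when adjusted over the list alone). Oaz3 fell 1.30-fold, Tssk6 1.21-fold and Odf1 1.24-fold, and Cylc2 rose 1.76-fold. The calls of Tssk6, Odf1 and Cylc2 were lost when any 1 of 3, 5 and 6 arrays was left out (adjusted p up to 0.0652, 0.0851 and 0.0766). The protamines Prm1 and Prm2 and the transition protein Tnp1 did not pass, at 1.17-fold higher (95% interval 0.989 to 1.39), 1.06-fold higher (0.947 to 1.18) and 1.02-fold lower (0.904 to 1.14), nor did the acrosomal Acrv1 (adjusted p = 0.271). Prm1 was called higher with array weights (0.0153), the authors' scaling factors (0.0390) and without R replicate 5 (0.0474). Camera's adjusted p was 0.791, 0.791 and 0.967 for the 3 stages.

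The sperm tail list was called higher. Of 28 flagellum and dynein genes 10 rose and 0 fell (15 and 1 when adjusted over the list alone), with a median of 0.25 (0.04 with the array median as reference). Camera gave an adjusted p of 2.6e-04 (adjusted p = 0.78 with an estimated correlation). Spag17, of the central pair of the axoneme, rose 1.85-fold, the dynein chain genes Dnaic1 and Dnah1 1.29-fold and 1.20-fold and Spef2 1.22-fold. The latter 3 lost their calls with the array median as reference (adjusted p = 0.0884, 0.651 and 0.391), and Dnah1 also over the mean of its probes (0.172). The list's median was 0.29 with the slide as a block, 0.35 within slide 1 and 0.23 within slide 2. The 20 genes of the piRNA pathway, which silences transposons, had 1 member higher and 4 lower, with the same counts when adjusted over the list alone (camera adjusted p = 0.673).

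**Figure D3:**
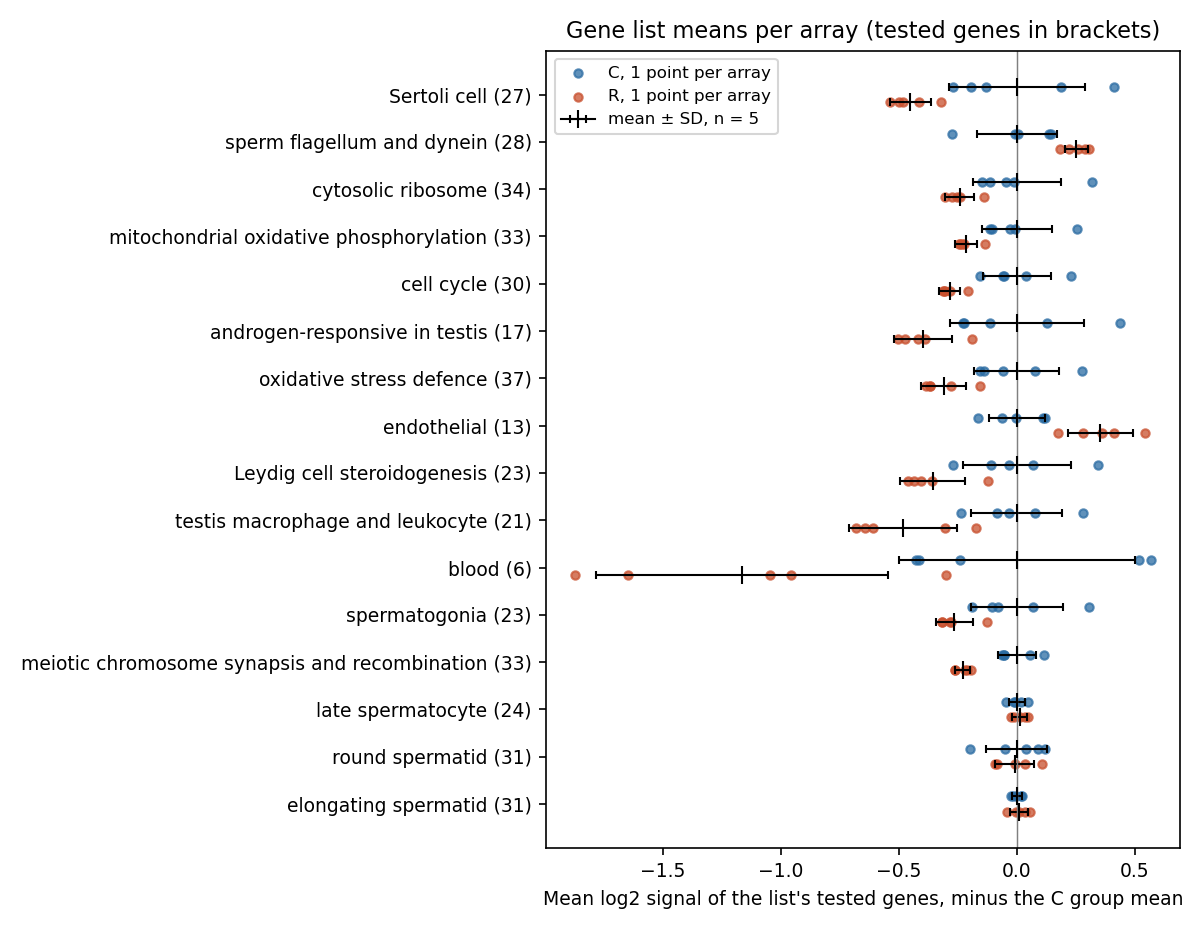
Mean log2 signal of each gene list's tested members per array, minus the C group mean, with the mean ± SD of 5 arrays per group. The lists called by camera stand in the upper part, and the lower part shows 5 germ cell lists, of which late spermatocytes average 4.03 in C and 4.04 in R before centring.

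The lists of the oxidative stress defence and the cell cycle were called lower in R. Of 37 genes of the oxidative stress defence 16 fell and 2 rose (17 and 3 when adjusted over the list alone), with a median of −0.37 (camera adjusted p = 0.00544, adjusted p = 0.78 with an estimated correlation). Nfe2l2, the regulator that induces antioxidant enzymes, fell 1.73-fold, its target Nqo1, above background on 3 R arrays, 1.83-fold, Gstp1 1.63-fold and Prdx4 1.44-fold. Cat was 1.44-fold and Gpx4 1.20-fold lower, each losing its call when any 1 of 4 arrays was left out (adjusted p up to 0.0586 and 0.0653), and Sod1 did not pass (adjusted p = 0.0923), though it was called lower with the slide as a block (0.0230), the array median as reference (0.0350) and quantile normalisation (0.0479). Of 30 cell cycle genes 15 fell and 2 rose (18 and 2 when adjusted over the list alone), with a median of −0.33 (camera adjusted p = 0.00309, adjusted p = 0.78 with an estimated correlation). Cdk1 fell 1.58-fold, Cdk2 1.51-fold, Mcm4 1.70-fold and Pcna 1.32-fold. Medians with the slide as a block, within slide 1 and within slide 2 were −0.52, −0.63 and −0.22 for the stress defence and −0.35, −0.41 and −0.24 for the cell cycle. Without C replicate 2 the median of the stress defence was −0.24.

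The ribosomal and oxidative phosphorylation lists were called lower with smaller medians. Of 34 ribosomal protein genes 13 fell and 0 rose, with the same counts when adjusted over the list alone, and a median of −0.21 (camera adjusted p = 3.9e-04, adjusted p = 0.78 with an estimated correlation). Rps14 fell 1.59-fold, the testis-expressed Rpl10l 1.42-fold, Rps7 1.30-fold and Rpl7 1.20-fold, and many pseudogenes of this family may share their signal. Of 33 genes of oxidative phosphorylation 15 fell and 0 rose (16 and 0 when adjusted over the list alone), with a median of −0.21 (camera adjusted p = 0.00244, adjusted p = 0.78 with an estimated correlation, 0.0797 with quantile normalisation). Cyc1 fell 1.45-fold, Atp5pb 1.39-fold, Atp5c1 1.38-fold and Sdhd 1.34-fold. Medians with the slide as a block, within slide 1 and within slide 2 were −0.28, −0.37 and −0.16 for ribosomes and −0.25, −0.32 and −0.14 for oxidative phosphorylation. Without C replicate 2 they were −0.14 for ribosomes and −0.13 for oxidative phosphorylation. Both were −0.42 with the array median as reference and −0.14 with quantile normalisation. The 27 glycolysis genes had 2 higher and 5 lower, with the same counts when adjusted over the list alone (camera adjusted p = 0.832).

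Genes of growth signalling, imprinting and cell death moved both ways, where 34.4% of all genes were called. Camera called none of these lists. Of 34 insulin, IGF and nutrient signalling genes 6 rose and 7 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.948). Pik3ca, a catalytic subunit of phosphoinositide 3-kinase, rose 2.82-fold and Ppargc1a, a regulator of mitochondrial biogenesis, 1.64-fold. Igf2r fell 1.41-fold and Sirt1 1.54-fold, though another probe of Sirt1 was called the opposite way and the call was lost over the mean of its probes (adjusted p = 0.174). Igf2, above background on 4 R arrays, was 1.51-fold lower (adjusted p = 0.0298, up to 0.069 when any 1 of 6 arrays was left out, 0.0555 over the mean of its probes and 0.0736 with array weights), and Igf1 differed by −0.01 ± 0.08 (SE). Of 30 imprinted genes 10 rose and 10 fell (10 and 12 when adjusted over the list alone, camera adjusted p = 0.948). Impact fell 1.49-fold, Peg12 rose 1.28-fold (0.14 on the log2 scale and not called with the array median as reference), and H19 did not pass (adjusted p = 0.0785). H19 was called lower with the slide as a block (0.0165), the array median as reference (0.0323), quantile normalisation (0.0326) and without C replicate 4 (0.0213). Of 32 apoptosis and p53 genes 12 fell and 2 rose (14 and 2 when adjusted over the list alone, median −0.18, camera adjusted p = 0.134, and 0.0227 with no filter). Xiap and Casp6 fell 1.95-fold and 1.85-fold, Bid and Sesn1 1.63-fold and 1.36-fold, and Bax did not pass (adjusted p = 0.0759). Bax was called lower with the slide as a block (0.010), over the mean of its probes (0.0105), with the array median as reference (0.0346) and without C replicate 3 (0.0498) or 4 (0.0389).

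Matrix and chromatin genes also split, with 34.4% of all genes called, and camera called neither list. Of 29 extracellular matrix genes 7 rose and 5 fell (9 and 9 when adjusted over the list alone, camera adjusted p = 0.717). Col1a1, the main fibrillar collagen, rose 2.45-fold, Pdgfrb 1.96-fold and Col1a2 1.51-fold, while fibronectin (Fn1) fell 1.37-fold. Col1a2 was not called with the array median as reference (adjusted p = 0.0682). In C replicate 4 Col1a2 (3.03) lay above R replicate 1 (2.95), and Col1a1 (0.41) lay close to R replicate 1 (0.49). Of 39 genes of DNA methylation and histone modification 10 rose and 5 fell, with the same counts when adjusted over the list alone (median 0.07, camera adjusted p = 0.134). The acetyltransferase gene Crebbp rose 1.48-fold, Kat2b 1.34-fold and the methyltransferase gene Ezh2 1.32-fold, whose 4 other probes gave the same sign at 2 and whose log2 change was 0.40, and 0.26 over the mean of its probes. Suz12 fell 1.34-fold, but another of its probes was called the opposite way and the call was lost over their mean (adjusted p = 0.125). With the array median as reference Kat2b and Ezh2 were not called (adjusted p = 0.0532 and 0.0748).

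**Figure D4:**
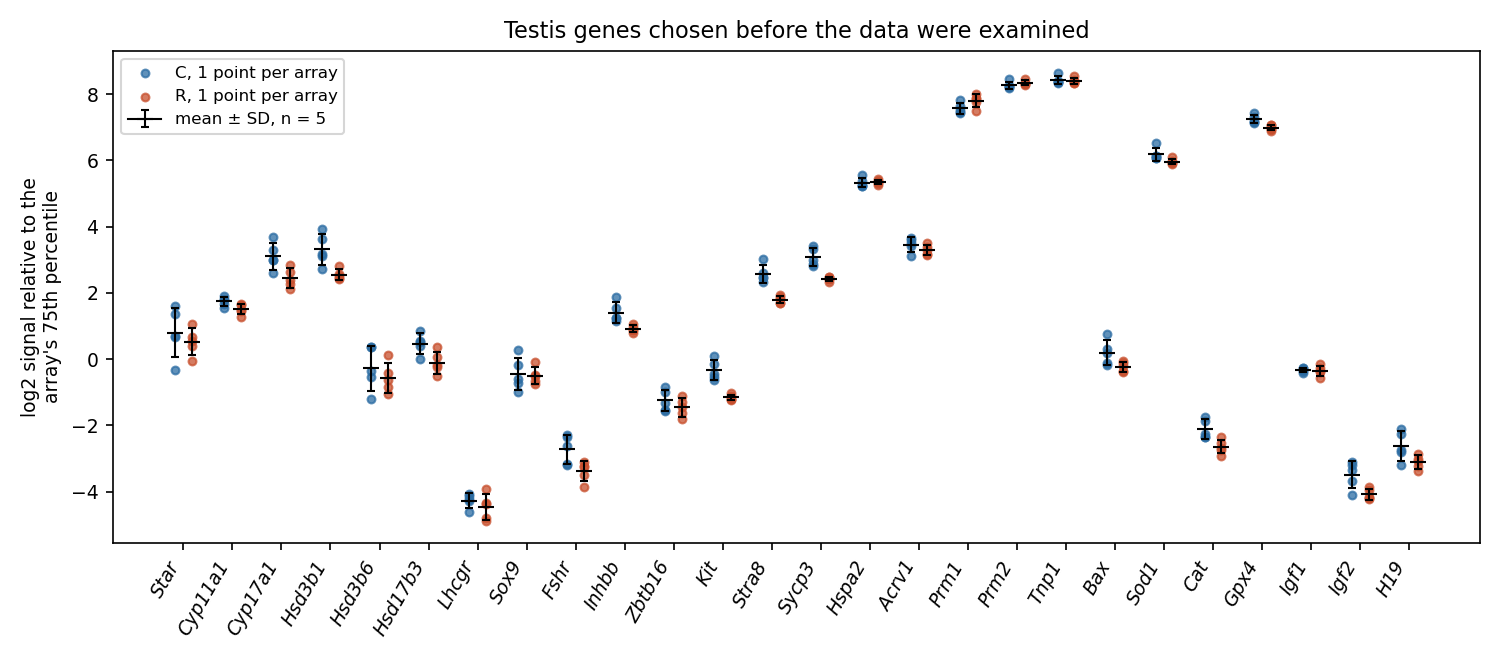
Log2 signal relative to the array's 75th percentile for tested testis genes chosen before the data were examined, with 1 point per array and the mean ± SD of 5 arrays per group. Kit averages −0.33 in C and −1.15 in R, while Tnp1 averages 8.42 and 8.40.

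Across the lists, 11 of 33 were called by camera, 9 lower and 2 higher, and 0 with an estimated correlation (lowest adjusted p = 0.78). Limma's fry, which asks only whether a list moves on balance, called 15, and the exact permutation test of list means called 16 (lowest adjusted p = 0.0291). With the slide as a block 10 lists were called, within slide 1 there were 13 and within slide 2, where the 1 R array has no replicate and is assumed to vary like the C arrays, there were 11. Under the table's grouping, where no probe was called, camera called 14. The median, mean and camera direction differed in sign for the imprinted, immediate early, epididymal, late spermatocyte, round spermatid, elongating spermatid, DNA repair and circadian lists, none of which was called.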

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

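The tests of chance splits, of the slide and of exchanged labels for the call counts, and that of a lower share of all non-germ cells, were chosen after the results were seen, as were the genes entered in the search for stray arrays and the unadjusted count used for the exchange, and the trend with gene length had been seen before its test was set.

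The labelled groups differed at 13059 probes. Of 100 splits of the 10 arrays into 5 and 5 (of 126 possible), the labelled split included, 1 called as many, and the highest of the others called 0. This argues against a random division of the arrays if the 10 animals are independent, which the unknown litters leave open. A share under 1 in 100 could not be reached, and the other splits mix both labels, which widens the spread within a side. With the slide as a block 17853 probes were called, which argues against the slide as the whole source, and a test that left out C replicate 2 was set aside after its value was seen (12833 probes). An exchange of labels between R replicate 1 and C replicate 5, which the authors' deposited table implies, stays open. That grouping called 0 probes, with 2567 at an unadjusted p under 0.05. Without these 2 arrays 6116 probes were called. On principal component 1 R replicate 1 (49.2) and C replicate 5 (−29.5) lay with their labelled groups. The table's grouping is the more even over slides, with 3 test and 3 control arrays on slide 1 and 2 of each on slide 2. None of these values decides which record is right. If the table were right, the split by label could follow another factor than diet, and fostering, litter, kit size and RNA integrity stay untested.

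The Sertoli list, the Leydig list and the macrophage and leukocyte list were called lower in R by camera but not with an estimated correlation (adjusted p = 0.78). The calls of the latter 2 were lost with the array median as reference (0.0719 and 0.115). That of macrophages and leukocytes was also lost without C replicate 2 (0.0728). Blood genes were lower too (median −0.92), and whether residual blood carried part of the leukocyte genes was not tested. A lower share of all non-germ cells would lower endothelial, peritubular myoid and matrix genes alike, but their means differed by 0.35 (exact permutation p = 0.00794), 0.06 (0.556) and 0.11 (0.190). Because the endothelial list had already been called higher when this comparison was set, its outcome was known and it is no independent test. That list was also dim, with a mean log2 signal of −2.37 in C. The endothelial median was 0.14 with the array median as reference and 0.18 with quantile normalisation (camera adjusted p = 0.0514). The array median as reference moved the median over all genes from −0.03 to −0.23, so the signs of the myoid and matrix differences depend on the reference. Their gap to the Sertoli list does not. Attached fat, whose markers averaged −2.07 in C and −1.23 in R (0.103), was not tested and could have raised the endothelial genes. The spike-in level, which unequal input or labelling would move, differed by −0.17 over both slides, less than the larger SD of a group (0.27). On slide 1 it was 1.93 and 2.43 in the C arrays and 1.61 to 2.10 in R. On slide 2 it was 1.75 to 1.94 in C and 1.65 in R replicate 5. The pooled difference therefore does not exclude unequal input or labelling. Taking out the trend with gene length left the median of the 71 members at −0.47 (−0.46 before), which argues against that trend as the cause. A lower share of all non-germ cells and fewer or less active Sertoli cells, Leydig cells, macrophages or other leukocytes remain candidate explanations. So do unequal input or labelling, RNA integrity, base composition and the open question of the labels, and these data cannot separate them.

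Of 334 groups of 5 arrays tested for an array far from the rest, 34 had such an array, where chance gives 16.7, and 14 of the 34 involved C replicate 2. The following values are the gap of the extreme array to its nearest neighbour as a share of the group's range.

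C replicate 2 stood apart on principal component 1 (0.857) and in the spike-in level (0.719, at 2.43 against a mean of 1.85 in the other C arrays). It stood apart in the means of oxidative phosphorylation (0.718) and ribosomal genes (0.712). Among genes it was high in Sod1 (0.841), Rpl7 (0.829), Fn1 (0.83), Tnp1 (0.799), Prm2 (0.797), Atp5c1 (0.761) and Rhox13 (0.73). It was low in Itgam (0.788), Flt1 (0.727) and Rhox8 (0.726). C replicate 1 was low in Zpbp2 (0.89) and in the piRNA list mean (0.774).

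R replicate 2 was high in the means of the adipocyte (0.819), oxidative phosphorylation (0.799), spermatogonial (0.796), cell cycle (0.728) and Leydig lists (0.712). It was also high in Mcm4 (0.844), Cfd (0.753), Xiap (0.745), Cst9 (0.722) and Plin4 (0.711). R replicate 5 was low in Pik3ca (0.968), Il22ra1 (0.927), Rhox8 (0.817) and Gabra2 (0.772). R replicate 4 was low in Cdk1 (0.864) and in the immediate early list mean (0.751), and R replicate 3 was low in the circadian list mean (0.736). R replicate 1 was high in Nqo1 (0.837).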

How the results depend on the processing

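The table's grouping, its version with the slide as a block, the omission of the 2 arrays it places otherwise, each slide alone and the table's own test on the labelled groups were chosen after the data were seen, while all other settings were planned.

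Under the table's grouping, with or without the slide as a block, limma called 0 probes, 0 by the study's criterion and 0 genes (2567 and 2450 probes at an unadjusted p under 0.05), since 2 arrays change sides. Without those 2 arrays 6116 probes, 3289 by the study's criterion and 2291 genes were called over fewer arrays. Slide 2 alone, with 1 R array assumed to vary like the C arrays, called 0 of each (8750 probes at an unadjusted p under 0.05). By the study's criterion 2539 probes were called with normexp, 8136 on slide 1 alone and 1408 past 2-fold, against 5309. Without the filter 3786 genes were called, and 89 of 105 called named genes kept the call. Camera called 7 lists with the array median as reference and 0 with an estimated correlation. Spata16 turned to −0.00361 with the array median as reference. Apart from the effect of fewer arrays, another grouping or a stricter fold, the cause was not tested.

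Without each array in turn, the count ranged from 9245 to 13550 probes, from 3746 to 6037 by the study's criterion, from 3790 (without R replicate 4) to 6310 genes and from 10 to 12 lists. Of 105 called named genes 84 kept the call without each array. Across all settings 0 values of called lists and 1 of called genes changed sign, and so did 105 of uncalled lists and 47 of uncalled genes. With the slide as a block 103 of the 105 kept call and sign. The table's own test called 13018 probes between the labelled groups. No paired analysis was possible because the labels give no replicate numbers, and the numbers used here only follow the order of the samples. Genes near background, such as Angptl7, Vmn1r31 and Lyz2, limit what their folds can show.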

Other observations

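The comparisons by chromosome and by probe class were chosen after the data were seen, and the X-linked shift was known before its tests were run.

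Of the gene lists described nowhere else, none was called by camera. Of 25 heat shock and unfolded protein genes 9 fell and 2 rose (11 and 3 when adjusted over the list alone), with a median of −0.20 and an adjusted p of 0.103 (0.0177 with no filter). Of 16 glucocorticoid response genes 3 fell and 2 rose (4 and 2 when adjusted over the list alone), with a median of −0.27 and an adjusted p of 0.24. Of 19 interferon genes 4 fell and 1 rose (3 and 1 when adjusted over the list alone, adjusted p = 0.368). Of 16 immediate early genes, which respond to handling, 4 rose and 1 fell (4 and 3 when adjusted over the list alone, adjusted p = 0.541). The 34 DNA repair genes had 5 higher and 4 lower (4 and 1 when adjusted over the list alone, adjusted p = 0.791). The 16 circadian genes had 2 higher and 2 lower (2 and 1 when adjusted over the list alone, adjusted p = 0.909).

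Genes on chromosome X were lower in R as a group. Of 656 X-linked genes 249 fell (38.0%) and 33 rose (5.03%), against 19.3% and 14.8% of autosomal genes, and the medians were −0.28 and −0.02. The X minus autosome difference per array was 0.14 ± 0.15 in C and −0.14 ± 0.06 in R (SD, n = 5, exact permutation p = 0.00794, the smallest possible). No other chromosome had a median outside −0.07 to 0.05. The difference between the groups was −0.36 within slide 1, −0.23 within slide 2, −0.19 without C replicate 2 and −0.16 under the table's grouping.

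With the slide as a block the X difference was −0.32, which argues against the slide as its source. Of 10000 autosomal sets matched on signal 0% had a median as low, the lowest being −0.10, which argues against signal level. Fewer Sertoli and interstitial cells alone would leave germ cell genes of X and autosomes alike, but 8 X-linked members of the germ cell lists had a median of −0.30 against −0.0036 for 177 autosomal members (1-sided permutation p = 0.00842). That permutation treated genes as independent and did not match them on germ cell stage. The spermatogonial and meiotic lists had medians of −0.21 as wholes, so the difference may follow stage rather than X. With 8 of the 656 X-linked genes, the comparison cannot exclude fewer Sertoli and interstitial cells for the shift as a whole. A shift in the share of early germ cells, which transcribe X before it is silenced in meiosis, may be a biological hypothesis, and it was not tested. Fewer Sertoli and interstitial cells, base composition, transcript length, RNA integrity and the open question of the labels also remain.

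Probes that took no gene name here were higher in R more often than lower, at 31.5% against 8.89% of 9839 probes, with a median of 0.23 (exact permutation p = 0.00794, adjusted p = 0.0159). Their median was 0.03 with the array median as reference and 0.13 with quantile normalisation. Probes of long non-coding RNA were called higher at 18.2% and lower at 7.29% of 1606 (exact permutation p = 0.0794), with a median of 0.12 that was −0.09 with the array median as reference and 0.03 with quantile normalisation, and those of protein-coding genes at 17.2% and 21.5% of 22123. The unnamed probes were dimmer, with a median log2 signal of −2.38 against −0.53 for protein-coding ones.

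Across genes, which are not independent replicates, the log2 change rose weakly with gene length (Spearman's rho 0.10), from a median of −0.06 over the shortest 1680 genes to 0.10 over the longest 1680.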
